A study of Mus musculus with 6 samples.

How the data were processed

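RNA-seq libraries of A2B5-selected spinal cord OPCs from 3 GDE3 KO and 3 WT samples were analysed, grouped by genotype and numbered by their titles. Per the submitters' processing notes, FastQC, TopHat2 2.1.1, Cufflinks 2.2.1 and Cuffdiff 2.2.1 were used with the mm10 build. The deposited files hold 1 transcript assembly per library, in which the authors' assembler gives each transcript its exons, coverage and FPKM, a fragment density scaled to transcript length and library size. The deposited transcripts carry identifiers made separately for each library and no gene names, so they were matched by position to the GENCODE M21 basic annotation, which is on the same build. Read counts are not in the files used here, so depth is known only relatively, from coverage per unit of FPKM (0.759 to 1 of the deepest library), and no count model or counting interval was used. Strandedness of the libraries is not given in the sources used here.

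Gene values were made from assembled transcripts of 300 nt or more. For each of 30975 genes with at least 200 exonic bases that no other annotated gene shares on either strand, the FPKM of the transcripts on the gene's strand or without a strand was summed at each such base and averaged over these bases. Before the data were examined the gene value had been set as the sum of FPKM over a gene's transcripts. The files turned out to hold gene fragments, and a gene in several pieces is counted several times by such a sum. WT replicate 1 had 36.8% of its transcripts under 300 nt, against 2.16% to 6.61% in the others. The base average therefore departs from the gene value set beforehand. It was chosen for this reason after seeing the files and before genotypes were tested, without comparing its spread between replicates with that of the sum. The 300 nt minimum, set beforehand for a gene's longest transcript, was applied to every transcript after the agreement between libraries with and without it had been seen. Results with the sum, without the minimum on the longest transcript, are given as an alternative (0 genes called, against 1). Transcripts under 300 nt held 97.95% (KO replicate 1) to 99.96% (WT replicate 1) of the summed FPKM of a library. Short fragments can therefore dominate a sum over all transcripts, and changes seen with it may reflect them. A base average falls when part of a gene is not assembled, so a difference can reflect assembled extent as well as level, and a 0 means that nothing was assembled. Genes at 5 FPKM or more in 5 libraries and at 0 in the sixth numbered 81. Genes that share exons, and copies that share reads, remain uncertain.

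Genes with a mean of 1 FPKM or more over the 6 libraries (12036) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend, two-sided, genotype as the only term) with Benjamini-Hochberg adjustment at 0.05. Fold changes on this scale understate the change of low genes. Of 26 gene lists written before the data were examined, 25 had at least 3 tested members and were tested with camera at a preset inter-gene correlation of 0.01, adjusted over lists. The erythroid list had too few. The lists held 725 genes, of which 719 were quantified. Values are given as mean ± SD over 3 libraries, or per library where a library is listed at 0. Named genes followed a rule fixed before the data were examined: the GDE family, Cntfr, Lifr, Il6st, Cntf, Socs3 and Stat3, then up to 10 genes per direction past the threshold without overlap between genotypes, filled to 8 by unadjusted p among genes at 2 FPKM or more, and from each list the 2 to 4 members with the smallest p. One gene that the rule takes is not reported here. Mfsd11, Mki67, Trem2, Prss23os, Hddc3, Tshz2, Top2a, Gfap and the mitochondrial genes were named after their values were seen. Isoform fractions were not tested because transcript identifiers are not shared between libraries.

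Same-numbered KO and WT libraries deviated together from their group means (r across genes = 0.371, 0.198 and 0.288 for numbers 1, 2 and 3, against -0.273 to 0.0259 for other combinations; genes are not independent replicates). The numbers come from the titles, and the identifiers in the descriptions share a middle number of 3 for pair 1 and of 4 for pairs 2 and 3. The numbers were therefore taken to pair the samples, and fits with the replicate block are given where they change a call. The first principal component (36.7% of the variance) set both replicate 1 libraries apart from the other 4. Alternatives covered pseudocounts, filters, scaling, the block, the identifier number, array weights, robust estimation, the length minimum, sex chromosomes, left-out libraries and other gene values.

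The code was tested on simulated data before use. For KO against WT with 12036 genes and 200 changed genes, the genotype fit recovered 18% of changes of 1 log2 unit and 78% of changes of 2 log2 units with 0 false calls, and the fit with the replicate block 57% and 93% with 16 false calls among 178. A further gene list was shifted by 0.7 log2 units, and calls within it were not counted as false. Noise was drawn independently for each gene, at the residual spread of the fit with the block, around the measured replicate deviations. The simulation held no assembly gaps, so these rates check the code and need not hold for the data.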

Results

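RNA-seq was made from oligodendrocyte precursor cells (OPCs), the proliferating glial cells that give rise to myelinating oligodendrocytes. The cells were taken from the spinal cords of C57BL/6 pups at postnatal day 0.5 by magnetic selection for A2B5, a surface ganglioside epitope of glial precursors. They were kept for 16 h in a proliferative medium with 10 ng/mL PDGF, 10 ng/mL CNTF and 5 µM forskolin. There were 3 libraries from GDE3 knockout (KO) cells and 3 from wild-type (WT) cells. GDE3, encoded by Gdpd2, is a membrane enzyme that cleaves the glycosylphosphatidylinositol (GPI) anchor of surface proteins, and the series title links it to OPC proliferation through release of the soluble CNTF receptor alpha. Each library had its own transcript assembly, with 33604, 41319 and 32098 transcripts in KO replicates 1 to 3 and 56807, 35036 and 32693 in WT replicates 1 to 3. The WT replicate 1 assembly was in shorter pieces, with a median transcript length of 438 nt against 1173 to 1830 nt in the other 5 libraries. The number of reads is unknown, but coverage per unit of FPKM gave relative depths of 0.935, 0.882 and 0.988 for the KO libraries and 0.759, 0.960 and 1 for the WT libraries. Nothing in the labels says whether the replicates came from separate litters or animals, so the p-values measure the spread between these libraries, which may be partly technical. Sex is not in the labels used here, but Xist and Ddx3y, given below, set WT replicate 1 apart from the others in sex.

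The first question was whether the libraries carried the deletion their labels name. Gdpd2 (ENSMUSG00000019359.14, chromosome X, 100729942 to 100738894, plus strand, mm10) has 16 annotated exons. Exons 9 and 10 (100734170 to 100734252 and 100734364 to 100734514) were assembled in full in WT replicates 2 and 3 and in none of the 3 KO libraries. Exon 8 was assembled over 0%, 0% and 2.69% of its length in the KO libraries. WT replicates 2 and 3 had 3.46 and 3.74 FPKM over these exons. WT replicate 1 held a single Gdpd2 fragment of 145 nt, which held exon 9 in full, 19.5% of exon 8 and 21.9% of exon 10, and was listed at 26.5 FPKM. The KO libraries kept sequence on both sides: exon 5 was spliced to exon 11 in KO replicates 1 and 3, and exon 6 to exon 11 in KO replicates 2 and 3. Neither junction was present in a WT library. In KO replicate 1 exons 7, 8 and 13 to 16 were also at 0% and exon 6 was assembled over 7.07%. The absence of exons 9 and 10 alone is therefore not distinct from other gaps in that library, where the junction was at 1.15 FPKM. The level over the whole gene did not separate the genotypes. It was 0.667, 1.497 and 1.78 FPKM in the KO libraries and 0, 2.79 and 2.85 FPKM in the WT libraries, where the 0 of WT replicate 1 reflects the 300 nt minimum for assembled transcripts. The exact two-sided permutation test of 3 against 3 libraries gave p = 1, and 0.1 is the smallest p it allows. Over exons 9 and 10, with fragments of any length counted, the same exact permutation test gave p = 0.1. The labels name no deleted exons, and these were taken from the same assemblies as those absent from every KO library. This p was therefore largely fixed by the choice of exons and adds no support.

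**Figure D1:**
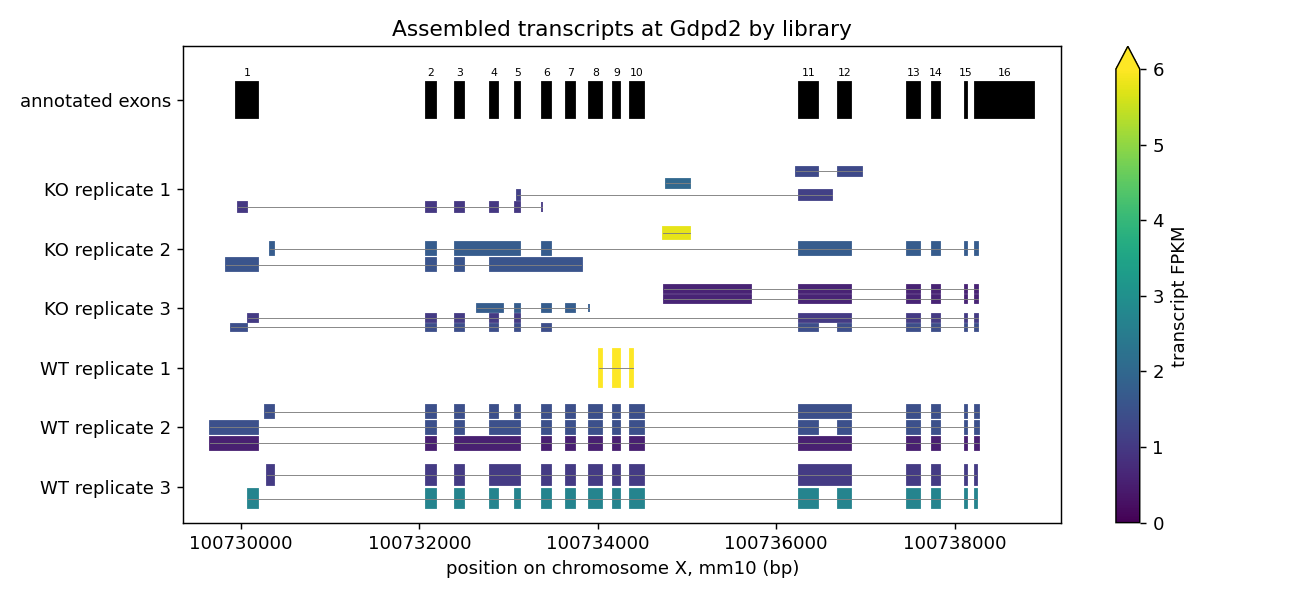
Assembled transcripts at Gdpd2 in each library, drawn to scale along chromosome X (mm10, bp), with the annotated exons numbered at the top and the fill giving the transcript's FPKM (values above 6 share the top colour). Exons 9 and 10 are covered in full in WT replicates 2 and 3, in part in WT replicate 1 (exon 9 and 21.9% of exon 10) and in no KO library, and the KO libraries join exon 5 or 6 to exon 11.

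The other family members and the genes around Gdpd2 differed by less than the limma test could call. Gde1, another glycerophosphodiester phosphodiesterase gene, had 76.9 ± 7.07 FPKM in KO and 74.4 ± 3.47 in WT (SD, n = 3 each). Gdpd1 had 21.3 ± 1.03 against 24.1 ± 1.83 FPKM, and Gdpd5, which encodes GDE2, had 3.20 ± 0.333 against 2.94 ± 0.842 FPKM. Their limma adjusted p was 0.9999 each. Gdpd3 averaged 0.301 FPKM over the 6 libraries and Gdpd4 was listed at 0 in all 6, both under the minimum for testing.

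Of 48 expressed genes within 5 Mb of Gdpd2, 22 were higher in KO and 0 had an unadjusted limma p under 0.05. Their median log2 difference was -0.0087, and limma's camera, which sets these genes against all others, gave an adjusted p of 0.505 over the 3 window sizes tried.

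The main comparison asked which genes differ between KO and WT OPCs. Of 12036 genes tested with limma, 0 were higher and 1 was lower in KO at a Benjamini-Hochberg adjusted p under 0.05, while 194 had an unadjusted p under 0.05, and 511 with the replicate number as a block, where 601.8 would be expected by chance. The gene that passed was Mettl23, which encodes a methyltransferase-like protein (ENSMUSG00000090266.10, chromosome 11, 116843278 to 116849740, plus strand). It was listed at 0 in the 3 KO libraries and at 6.25, 9.11 and 8.60 FPKM in the WT libraries (log2 difference -3.15 ± 0.18 SE on the log2(FPKM + 1) scale, limma adjusted p = 0.0202). With the replicate number as a block its adjusted p was 0.284, so that 0 genes passed. Leaving out KO replicate 2 or 3 or WT replicate 2 or 3 also ended the call (adjusted p = 0.0712, 0.0542, 0.0796 and 0.151), as did a pseudocount of 0.1 or 5 (0.0717 and 0.0821). It was also lost when FPKM was summed over a gene's transcripts, the form of the gene value set before the data were examined, which called 0 genes in either direction, although its log2 difference was then -3.91 (adjusted p = 0.969). A listed 0 is not evidence of absent RNA in these files. The neighbouring Mfsd11, a gene of the major facilitator family, was at 10.4 to 15.3 FPKM in the WT libraries and KO replicate 1 and at 1.94 and 0 in KO replicates 2 and 3. All 10 mitochondrial protein genes tested were listed at 0 in 4 of the 6 libraries, and Gapdh, the glycolytic enzyme, was listed at 0 in WT replicate 1 and at 60.4 to 116 FPKM in the others.

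Among genes that did not pass, those whose KO values all lay above the WT values were led by Cdk19, a kinase of the Mediator complex, with 11.8 ± 1.71 FPKM in KO against 3.78 ± 0.381 in WT (limma adjusted p = 0.278). Among the others were Dgkd, a diacylglycerol kinase (16.7 ± 1.39 against 9.91 ± 0.839 FPKM), Ss18l2 (14.7 ± 4.93 against 4.42 ± 1.72), the myeloid receptor gene Lilr4b (5.09 ± 0.497 against 2.96 ± 0.566), Card19 (24.7 ± 2.36 against 16.6 ± 2.13), the haematopoietic adaptor Fyb (3.17 ± 1.11 against 1.15 ± 0.155) and the purinergic receptor P2rx4 (7.62 ± 1.57 against 4.47 ± 0.621 FPKM). On the lower side, Tubb4b, a beta tubulin, had 66.6 ± 9.13 FPKM in KO against 207 ± 35.6 in WT (limma adjusted p = 0.383). The ubiquitin ligase Itch had 10.4 ± 0.364 against 18.1 ± 1.23, the thiolase Acat2 32.5 ± 6.17 against 100.8 ± 22.7, and the DNA replication licensing factor Cdt1 21.6 ± 1.11 against 38.9 ± 4.08 FPKM. Nit2 (8.61 ± 1.97 against 18.8 ± 0.941), the splicing regulator Mbnl1 (6.14 ± 0.745 against 10.8 ± 1.40) and Rufy3 (10.7 ± 1.11 against 17.7 ± 2.31 FPKM) completed the set. Of all tested genes 5.07% had no overlap between genotypes, where chance gives 10% if the pairing is ignored. For several of these genes the genotypes differed in how much of the gene was assembled. Cdk19 was assembled over 99.1% to 100% of its exonic bases in KO and 25.7% to 27.2% in WT, and Tubb4b over 28.0% to 29.7% in KO and 96.1% to 97.6% in WT. Averaged over assembled bases only, Cdk19, Tubb4b, Itch, Mbnl1 and Rufy3 changed direction, and the log2 difference went from 0.69 to 0.12 for Dgkd, from 0.65 to 0.14 for P2rx4, from 0.63 to 0.32 for Lilr4b and from -1.60 to -0.79 for Acat2. FPKM summed over all transcripts of a gene moved the median log2 difference of all genes to -0.25, and relative to that median Tubb4b, Itch, Rufy3 and Lilr4b changed direction, as did Cdk19 and Mbnl1 by less than 0.05.

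The CNTF receptor pathway, which the series title names, showed no RNA difference past the threshold. The title's link runs through release of the soluble receptor, a step on the protein that RNA levels do not measure. All cultures also held 10 ng/mL CNTF, so these values do not test that link. Cntfr, the gene of the GPI-anchored CNTF receptor alpha (ENSMUSG00000028444.17, chromosome 4, 41657498 to 41697040), had 15.9 ± 2.51 FPKM in KO and 14.8 ± 1.52 in WT (log2 difference 0.09 ± 0.15 SE, limma adjusted p = 0.9999). The signalling subunits Lifr (2.36 ± 0.792 against 2.49 ± 0.333) and Il6st (15.7 ± 1.30 against 16.2 ± 1.08), the transcription factor Stat3 (57.1 ± 6.59 against 58.1 ± 6.42) and the feedback inhibitor Socs3 (28.7 ± 4.52 against 27.7 ± 2.41 FPKM) were as close. Cntf itself was at 22.7, 1.87 and 21.1 FPKM in the KO libraries and at 0, 0 and 23.1 in the WT libraries. Of the 26 tested members of the CNTF receptor and JAK-STAT list, 16 were higher and 10 lower in KO, 0 passed over all genes and 0 adjusted over the list alone, and the camera adjusted p was 0.478. The members with the smallest p were Socs2 (2.28 ± 0.511 against 3.69 ± 1.76) and Bcl3 (2.43 ± 0.319 against 1.78 ± 0.859 FPKM).

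Because the study concerns proliferation, the cell cycle lists came next. Of 34 S phase genes 23 were lower in KO, and adjusted over the list alone 1 passed, Cdt1 (limma adjusted p over the list = 0.0126), against 0 over all genes. The list itself had a camera adjusted p of 0.121. Ccne2, a cyclin of the G1 to S transition, had 6.86 ± 2.33 against 10.7 ± 0.992 FPKM. Of 36 G2 and M phase genes 25 were higher in KO (camera adjusted p = 0.556; 0 adjusted over the list alone), with Aurkb at 41.0 ± 10.2 against 30.4 ± 4.18 and Ube2c at 69.7 ± 22.5 against 54.7 ± 24.8 FPKM. Within both genotypes replicate 1 stood apart: Mki67, the proliferation marker, was at 14.2 and 12.1 FPKM in KO and WT replicate 1 and at 67.4 to 73.7 in the other 4 libraries. Of 23 genes of G1 cyclins, CDK inhibitors and p53 targets 16 were lower in KO (camera adjusted p = 0.717), with Cdkn1c at 40.8 ± 10.8 against 58.6 ± 4.11 FPKM and Ccnd2 at 21.8 ± 1.91 against 19.3 ± 1.34.

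Of the 25 gene lists tested, 5 passed with the preset correlation and 0 with an estimated correlation or with fry. Microglia and macrophage markers were higher in KO for 20 of 20 tested members, with a median log2 difference of 0.69 (camera adjusted p = 3.05e-15; p = 0.0382 and adjusted p = 0.874 with an estimated correlation). The median was 0.43 without WT replicate 2, 0.42 without KO replicate 3 and 0.44 with a pseudocount of 5. Of its members 0 passed over all genes and 0 adjusted over the list alone; with the replicate block 1 passed over the list alone, the lipid receptor gene Trem2 (7.01 ± 3.26 against 3.07 ± 1.75 FPKM, limma adjusted p over the list = 0.00865). The complement genes C1qa and C1qb were at 13.2, 13.1 and 34.8 and at 14.02, 19.2 and 30.6 FPKM in the KO libraries, against 8.87, 6.11 and 8.12 and 10.9, 8.77 and 8.65 FPKM in WT. C1qc had 22.4 ± 11.9 against 8.62 ± 0.364 and Laptm5 10.8 ± 3.17 against 5.75 ± 0.678 FPKM. Interferon stimulated genes were higher in KO for 20 of 20 tested members (median 0.43, camera adjusted p = 9.31e-07; adjusted p = 0.874 with an estimated correlation), and the values of KO replicate 3 were the highest of the 6 libraries for the members named here. Isg15 was at 2.50, 1.23 and 18.7 FPKM in the KO libraries and 0, 1.26 and 1.34 in WT, and Bst2 at 9.57, 4.25 and 26 against 6.57, 3.63 and 5.25. Ifit3 was at 0.930, 1.15 and 9.88 against 0, 0.615 and 0.537, Rsad2 at 1.74, 0.356 and 4.03 against 0, 0.386 and 0.895, and Irf7 at 1.10, 0.653 and 5.74 against 0, 0.560 and 0.817. Without KO replicate 3 this list did not pass (median 0.13, camera adjusted p = 0.096). It passed with a median of 0.69 without KO replicate 2, 0.67 without the replicate pair 1, 0.27 over assembled bases only, 0.24 with a pseudocount of 5 and 0.14 with FPKM summed over all transcripts (-0.25 for all genes). The mean list scores of both lists lay above all 3 WT libraries in each KO library (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). For the interferon list this was nearly a tie, with 2.128 in KO replicate 2 and 2.109 in WT replicate 3, while KO replicate 3 had 3.434. For the microglia list the lowest KO score was 3.347 and the highest WT score 3.121. Scores without overlap were also found for the hypoxia and glycolysis list, above WT, and the GPI synthesis list, below WT, so that 4 of the 25 lists were separated where chance gives 10% if the pairing is ignored. The hypoxia and glycolysis list holds Gapdh, listed at 0 in WT replicate 1. The GPI synthesis list holds Pigp, listed at 0 in KO replicates 2 and 3. Each 0 moves its list's score toward separation, and the scores were not recomputed without these genes.

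**Figure D2:**
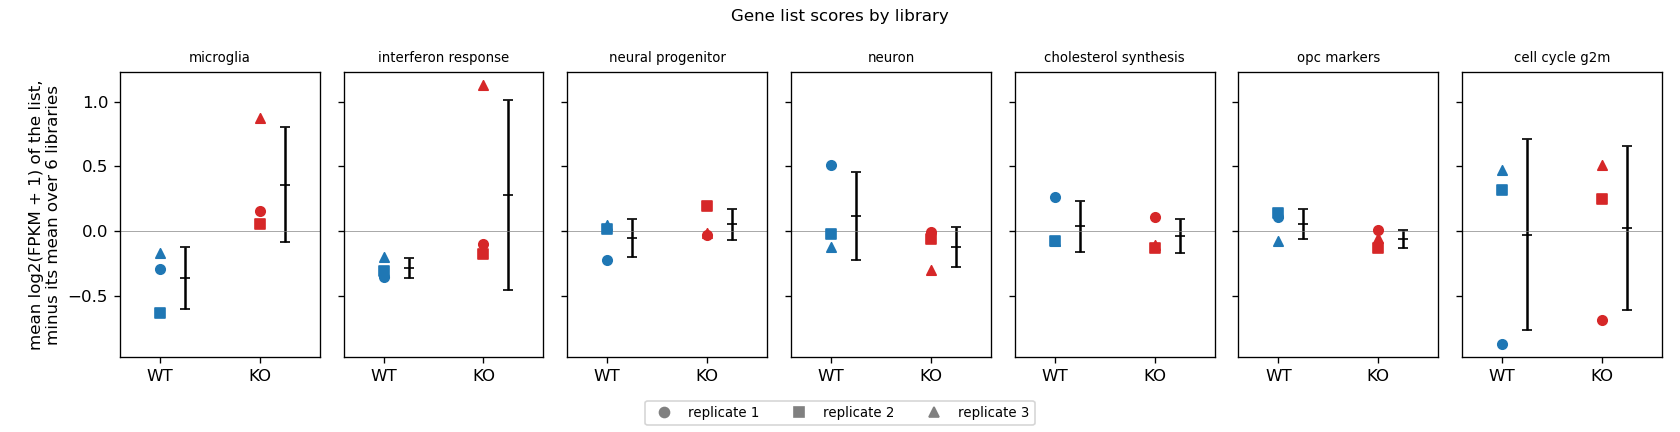
Gene list scores by library, as the mean log2(FPKM + 1) over the list minus its mean over the 6 libraries, with 1 point per library (WT left, KO right, symbols for replicates) and the mean ± SD beside them (n = 3). Microglia and interferon response scores of the 3 KO libraries lie above those of the 3 WT libraries, the interferon score of KO replicate 2 only just, and the G2 and M scores of both replicate 1 libraries lie below the other 4.

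Smaller shifts passed for 3 further lists, each lost with an estimated correlation (adjusted p = 0.874, 0.874 and 0.876 in the order given). Neuron and neuroblast markers were lower in KO for 20 of 23 members (median -0.12, camera adjusted p = 0.00718), with Dcx at 11.02 ± 1.18 against 13.8 ± 2.35, Elavl4 at 6.88 ± 0.894 against 8.42 ± 1.15, Nefm at 6.01 ± 1.502 against 16.5 ± 15.6 and Stmn3 at 68.7 ± 7.05 against 84.4 ± 20.0 FPKM. Radial glia and neural progenitor markers were higher for 14 of 17 (median 0.14, camera adjusted p = 0.0157), with the intermediate filament gene Nes at 62.6 ± 4.03 against 51.4 ± 1.52, Hey1 at 13.4 ± 1.79 against 11.5 ± 0.569, Irx3 at 5.52 ± 1.48 against 4.35 ± 0.312 and Hes1 at 9.65 ± 3.83 against 6.66 ± 0.413 FPKM. Sterol and lipid synthesis genes were lower for 22 of 28 (median -0.12, camera adjusted p = 0.00718), with Hmgcs1 at 245.5 ± 68.6 against 342.4 ± 24.7, Lss at 48.3 ± 6.13 against 60.9 ± 5.87, Scd1 at 109.7 ± 11.4 against 123.9 ± 2.00 and Cyp51 at 103.8 ± 13.4 against 124 ± 19.0 FPKM. In each of the 3 lists 0 members passed over all genes and 0 adjusted over the list alone. These 3 calls depended on the gene value and on single libraries. With FPKM summed over all transcripts, the form of the gene value set before the data were examined but without its minimum on the longest transcript, none of the 3 lists passed (camera adjusted p = 0.309, 0.590 and 0.7996), with medians of -0.43, -0.14 and -0.0915 against -0.25 for all genes. Over assembled bases only, the progenitor and sterol lists did not pass (0.173 and 0.404). Without WT replicate 1 the medians were -0.02, -0.01 and -0.05 and none of the 3 lists passed (camera adjusted p = 0.477, 0.488 and 0.552). The neuron list was also lost without KO replicate 3 (0.271), the progenitor list without KO replicate 2 (0.303), and the sterol list without KO replicate 2 or 3 (0.196 and 0.179). Array weights ended the progenitor call (0.190), no length minimum the sterol call (0.0669, with its median still at -0.12), and leaving out the replicate pair 1 the neuron and progenitor calls (0.0575 and 0.250). OPC markers were lower for 19 of 27 members but did not pass (median -0.12, camera adjusted p = 0.0529; 0.0155 with the replicate block), with Lhfpl3 at 85.0 ± 6.91 against 114.4 ± 13.3 and Neu4 at 1.78 ± 0.258 against 2.32 ± 0.1997 FPKM. With the block, 9 lists passed: these 6 together with the astrocyte (adjusted p = 0.0303), endothelial and mural (0.0461) and Schwann cell and neural crest lists (0.0456). With an estimated correlation 0 lists passed under the block either, where the microglia list had p = 0.0638.

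The remaining lists did not pass in the fit on genotype, and 0 of their members passed over all genes or adjusted over the list alone. Astrocyte markers were higher in KO for 18 of 25 members (camera adjusted p = 0.0715), with the growth factor receptor gene Fgfr3 at 23.6 ± 6.51 against 15.9 ± 4.26 and Agt at 8.15 ± 1.23 against 6.51 ± 0.636 FPKM. Genes of committed and myelinating oligodendrocytes were lower for 19 of 31 (0.556), with Aspa at 1.18 ± 0.130 against 2.58 ± 1.00 and Bcas1 at 185.1 ± 4.39 against 225.2 ± 17.4 FPKM. Endothelial and mural markers were higher for 9 of 13 (0.238), with Cdh5 at 4.02 ± 1.93 against 2.75 ± 1.55 and Esam at 2.42 ± 0.898 against 1.73 ± 0.516. Schwann cell and neural crest markers were lower for 11 of 15 (0.167), with Postn at 8.27 ± 2.24 against 11.1 ± 2.74 and Foxd3 at 1.55 ± 0.303 against 2.1 ± 0.523. Meningeal and fibroblast matrix genes were lower for 11 of 21 (0.917), with Igf2 at 2.03 ± 0.347 against 3.78 ± 1.97 and Mgp at 2.14 ± 1.00 against 9.24 ± 10.9 FPKM.

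Substrates and enzymes of the GPI pathway were tested because GDE3 acts on GPI-anchored proteins. Genes of GPI-anchored surface proteins were lower for 23 of 41 members (camera adjusted p = 0.717), with Cntn4 at 2.14 ± 0.305 against 2.77 ± 0.0737 FPKM and Bst2 as given above. Enzymes of GPI synthesis were lower for 14 of 26 (0.717). Among them Dpm2 was at 30.6 ± 3.22 FPKM in KO against 12.9 ± 5.96 in WT, and Pigp was at 4.75, 0 and 0 against 8.71, 8.94 and 8.32, neither past the threshold. The log2 difference of Dpm2, 1.30, was 0.0457 over assembled bases only and 0.0263 with FPKM summed over transcripts. Pigp passed without KO replicate 1 (limma adjusted p = 0.00189) and without the replicate pair 1 (0.0119). Growth factor and MAPK feedback genes were split 9 to 9 (0.926; median -0.02 with an upward test direction), with Etv1 at 9.93 ± 0.703 against 11.6 ± 0.475 and Dusp6 at 22.6 ± 1.24 against 20.3 ± 2.1 FPKM. Immediate early and dissociation stress genes were higher for 16 of 27 (0.917), with Ier5 at 12.2 ± 1.16 against 10.5 ± 0.737 and Hspa1b at 0, 0 and 0.223 against 7.75, 0.136 and 0.323 FPKM. Integrated stress and unfolded protein response genes were higher for 14 of 26 (0.556), with Phgdh at 160.2 ± 0.667 against 140.4 ± 6.99 and Cth at 4.06 ± 0.796 against 3.23 ± 0.659. Hypoxia and glycolysis genes were higher for 13 of 23 (0.478), with Egln3 at 9.81 ± 1.55 against 8.21 ± 0.822 FPKM. Oxidative phosphorylation subunits were lower for 30 of 51 (0.501), with Ndufb9 at 58.6 ± 25.4 against 133.7 ± 90.1 and Ndufa5 at 80.4 ± 12.01 against 98.5 ± 20.0. Cytosolic ribosomal protein genes were split 38 to 37 (0.917; median 0.01 with a downward test direction), with Rpl21 at 5.00 ± 1.44 against 8.59 ± 2.91 and Rps13 at 111.4 ± 44.2 against 220.9 ± 105.8 FPKM. The 4 tested GDE family genes had an adjusted p of 0.917. Of 8 sex-linked genes 4 were higher and 4 lower (0.917): Xist was listed at 15.4 FPKM in WT replicate 1 and at 0 in the other 5 libraries, while the Y-linked Ddx3y was listed at 0 in WT replicate 1 and at 6.96 to 9.90 in the others. The labels used here give no sex. These values are the pattern of female cells in WT replicate 1 and of male cells in the other 5 libraries. Pair 1 thus joined libraries that differed in sex, and fits without WT replicate 1 or pair 1 also left out the female library.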

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

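The tests of the microglia list against the neuron list and without KO replicate 3 and of the G2 and M genes were chosen only after the results were seen, whereas the second myeloid list and the counts over other splits were fixed before their results were seen.

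A signal in sequence that the gene values leave out was seen in the KO libraries. In intron 10 of Gdpd2, between the last exon absent from KO and exon 11, transcripts were assembled at 2.01 FPKM in KO replicate 1 (100734771 to 100735038), 5.79 in KO replicate 2 (100734736 to 100735036) and 1.19 in KO replicate 3 (100734746 to 100735721), and at 0 in the 3 WT libraries.

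Microglia and macrophage markers were higher in KO for 20 of 20 tested members, and KO replicate 3 alone is argued against as the cause, since the median without it was 0.42 (camera adjusted p = 8.18e-10, p = 0.0503 with an estimated correlation). More microglia or macrophages in the KO cultures may account for it: a second list of 51 myeloid genes, 0 of them in the first, had 38 tested members of which 36 were higher (median 0.55, p = 0.0464 with an estimated correlation, 0 members called), although A2B5 selection should leave few such cells. Scored in the same libraries, genes of the same cell type were likely to follow the first list. The second list therefore cannot tell more such cells from a change of activity in them. A lower share of OPCs would raise the lists of other cell types alike. In KO minus WT the score was 0.722 ± 0.29 SE for microglia and -0.241 ± 0.216 for neurons. It was 0.0913 ± 0.317 for astrocytes, 0.152 ± 0.135 for endothelial and mural cells and 0.106 ± 0.11 for neural progenitors. The microglia score exceeded the neuron score by 0.962 ± 0.41 SE in KO over WT. This excess was more than the 2 SE first set as the bound against a lower share of OPCs, but the exact permutation p was 0.1, the smallest possible. The bound was extended, after this value was seen, to hold without WT replicate 1, where the excess was 0.804 ± 0.442. With 3 libraries per genotype and SEs that ignore the pairing, 2 SE is a loose bound, so a lower share of OPCs is left open. The neuron score went the other way from such a cause, while 19 of 27 OPC markers were lower in KO. The splits are too few for a share under 0.05: the size of the list's median was 0.69 in the real split and at most 0.56 in the others, with 0.0199, 0.29 and 0.50 in the others that part all 3 pairs. By number of lists, the real split gave 5 lists past the threshold, 8 of the 10 splits gave as many, the highest other gave 14, and among the splits that part all 3 pairs the others gave 3, 5 and 3, while a change of gene activity with genotype stays open and untested.

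Genes called or listed at 0 by genotype came to 3, namely Mettl23 and Tshz2 at 0 in KO and Hddc3 at 0 in WT. Gaps in the assembly are a candidate explanation, since other splits of the libraries gave up to 14 such genes, and the others that part all 3 pairs 5, 0 and 6. Genes whose assembled share lay 30 points or more apart numbered 19 in the real split, 14, 11 and 19 in the others that part all 3 pairs, and up to 35 in a split that keeps pair 1 together. The real split called 1 gene, as many or more were called in 10 of the 10 splits, the highest other (KO replicates 1 and 2 with WT replicate 1) called 8, the others that part all 3 pairs called 3, 1 and 6, and the splits are too few for a share under 0.05; a genotype effect on these genes stays open.

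G2 and M genes were lower in both replicate 1 libraries. Lower depth is argued against as the whole cause, since the list's median was 1.14 log2 units higher in the other 4 libraries and the highest of 10000 lists matched on level reached 0.15. KO replicate 1 was also deeper than KO replicate 2 (relative depth 0.935 against 0.882) and had the lower list score (3.90 against 4.83). The fragmented assembly of WT replicate 1 is argued against too, since among KO libraries alone the difference was 0.99 against at most 0.18 in lists matched on level and length. Fewer astrocyte-lineage cells may contribute, as the astrocyte list was also lower in replicate 1 (camera adjusted p = 0.000538), but p was 0.189 with an estimated correlation, so this stays open. The identifiers of pair 1 hold a middle number of 3 and those of the others 4, but the labels do not say what this number stands for, and no biological explanation other than the cell makeup was tested.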

How the results depend on the processing

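The sum of FPKM over a gene's transcripts was the form of the gene value set before the data were examined, and became an alternative when the base average replaced it after the files were seen. The sum over all transcripts was run with transcripts matched by position and without the minimum on the longest transcript. It is therefore not exactly the value set beforehand. The sum over transcripts of 300 nt or more, the mean over assembled bases, the fit without the replicate pair 1 and the count of fragments of any length at Gdpd2 were chosen after seeing the data, and the other alternatives before. Reference transcripts only and isoform fractions were not run, because the transcripts carry no shared identifiers. Except where stated, the cause of a change was not tested. Depth limits these results in an unknown way, since read numbers are not known.

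The count of genes lower in KO, 1, became 0 with a pseudocount of 0.1 or 5, the replicate block, and either sum of FPKM. The count was also 0 with a minimum of 5 FPKM, a filter that removes Mettl23 before testing. It became 2 over assembled bases only, Mettl23 and Prss23os. At an unadjusted p under 0.05 with a 1.5-fold difference there were 60 higher and 42 lower. Without the replicate pair 1 there were 17 higher and 11 lower, among the higher ones the 10 mitochondrial genes listed at 0 in 4 libraries. Leaving out single libraries gave 0 to 10 genes higher and 1 to 6 lower, the highest of both without KO replicate 1, where the 10 higher were the mitochondrial genes. In both fits these are not 10 separate calls. All of them but mt-Cytb held one shared value in each library (1014 and 796.6 FPKM in KO replicates 2 and 3). The number of lists past the threshold, 5, became 0 with an estimated correlation and with fry, 9 with the replicate block, 2 with the sum over transcripts of 300 nt or more, and 3 (without KO replicate 2) to 11 (without WT replicate 2 or 3) when a library was left out. The sum over all transcripts also gave 5 lists, but only the microglia and interferon lists were in both sets. The other 3 were the integrated stress, ribosomal protein and sex-linked lists, and 159 genes had an unadjusted limma p under 0.05. The block changed no other call than those of Mettl23, of the lists that it added and of Trem2 within the microglia list. The microglia list passed under each of the 22 alternatives fitted with the preset correlation.

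The whole-gene log2 difference of Gdpd2, -0.11, was 0.48 with a pseudocount of 0.1, 0.84 with the sum over transcripts of 300 nt or more, 0.24 over assembled bases, and -0.76 to 0.22 without single libraries. It was -0.75 with the sum over all transcripts (-0.25 for all genes), -0.65 without a length minimum, -0.54 without the replicate pair 1 and -0.44 with array weights, and none of these values passed. The difference over exons 9 and 10 was -2.40 FPKM, and -6.78 with fragments of any length. The median of the genes around Gdpd2 was 0.0165 within 2 Mb, 0.00976 without a filter and 0.00465 with median ratio scaling.

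The sum over all transcripts, which transcripts under 300 nt can dominate, moved the median of all genes to -0.25 on the log2 scale. Relative to that median Ss18l2, Fyb, Bcl3, Hey1, Irx3 and the neural progenitor list kept their direction, so that their values below 0 follow from the shift. Gdpd1, Mbnl1, Lss, Hmgcs1, Scd1, Bcas1, Postn and the sterol list turned relative to it though not against 0. Against 0 it turned the direction of Il6st (0.57), Cdk19 (-0.28), Ss18l2 (-0.14), Lilr4b (-0.97), Fyb (-0.21), Tubb4b (0.12), Itch (0.0559), Rufy3 (0.59), Fgfr3 (-0.32), Bcl3 (-0.11), Cdh5 (-0.53), Esam (-0.34), Gapdh (-1.34), Isg15 (-0.27), Hey1 (-0.0938), Irx3 (-0.20), Dcx (0.53) and the neural progenitor list (-0.14). The sum over transcripts of 300 nt or more gave the same values for Il6st, Cdk19, Tubb4b, Itch, Rufy3, Bcl3, Cdh5, Hey1 and Dcx, and turned Lilr4b (-0.18) and Cth (-0.10). Over assembled bases Cdk19 (-0.25), Tubb4b (0.12), Itch (0.072), Mbnl1 (0.45) and Rufy3 (0.12) turned. Without the replicate pair 1, Gde1 (-0.00584), Lifr (0.0559) and Il6st (0.00452) turned, as did Il6st (0.00792) with array weights and Gapdh (-0.45) without a length minimum. Leaving out single libraries gave ranges through 0 for Gdpd5 (-0.0072 to 0.28), Gde1 (-0.0272 to 0.10), Cntfr (-0.0143 to 0.20), Lifr (-0.19 to 0.13), Il6st (-0.11 to 0.00313), Socs3 (-0.0509 to 0.17), Stat3 (-0.11 to 0.0645), Ddx3y (-0.0229 to 1.70) and the neural progenitor list (-0.00643 to 0.20).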

Other observations

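The largest contrast in the data followed the replicate pair and not genotype. Between the 4 libraries whose identifier holds a middle number of 4 and the 2 that hold 3, limma with genotype as a covariate called 213 genes higher and 43 lower, against 1 gene for genotype. The assemblies used were smaller in replicate 1, at 67.5 Mb in KO and 47.6 Mb in WT, against 74.9 to 82.2 Mb in the others. A base average falls with assembled extent, so part of these calls may reflect it. The contrast was not run over assembled bases only. Of 36 G2 and M phase genes 35 were higher in the 4 libraries and 24 passed, among them Mki67 (5.04-fold, adjusted p = 0.00646) and Top2a (2.06-fold, adjusted p = 0.0486). Gfap, the astrocyte intermediate filament gene, was at 57.9 and 32.1 FPKM in KO and WT replicate 1 and at 178.3 to 400.9 in the others (adjusted p = 0.0497). S phase genes did not follow (17 of 34 higher, camera adjusted p = 0.726).

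Cytosolic ribosomal protein genes were lower in the same 4 libraries for all but 3 of 75 (median -0.53, camera adjusted p = 4.24e-15), as were oxidative phosphorylation subunits for all but 2 of 51 (median -0.35, 3.42e-09) and immediate early and stress genes for all but 1 of 27 (median -0.55, 4.47e-08). With an estimated correlation the p-values were 0.023, 0.0543 and 0.202, and 0.057 for the G2 and M list, none past the threshold after adjustment over lists.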
